A study of Homo sapiens with 35 samples.

How the data were processed

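The deposited values were MAS5 signal intensities from Affymetrix 3' expression arrays, on a linear scale, with 1 value per probe set and array. Per the submitters' processing notes the signals were computed with MAS5, whose version was not stated, and no other upstream step was repeated or checked here. Each array as deposited had a 2% trimmed mean of 499.9, so all arrays had been scaled to the same target before deposition. The table held 54675 probe sets and 35 arrays. Present or absent calls were not analysed here.

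The platform table was used to name genes. 62 control probe sets were set aside, 41091 probe sets listed a single gene and were kept, 1801 listed several genes and 11777 listed none, and both of these kinds were left out. Where a gene had more than 1 probe set, the probe set with the highest mean signal was kept, which gave 19775 genes. TP53 and MAPK14 had no probe set that listed a single gene, so neither was analysed here and the knockdown was read from targets of p53. A gene entered a fit when at least 2 of its arrays had a signal above that array's own median. This left 14743 genes for the 23 first arrays and 14315 genes for the 12 repeat and SB203580 arrays. Values were fitted as log2(signal + 9), where 9 was the 20th percentile of all values. Folds of dim genes are understated on this scale, and array medians ran from 43.4 to 74.7.

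The 35 arrays were divided into 2 fits. The 23 first arrays formed 8 groups, from the vector line or the p53 shRNA line (p53i), DMSO or Nutlin-3, and no flagellin or flagellin. The 6 repeat arrays, whose titles end in A, and the 6 SB203580 arrays formed 4 groups in the vector line with Nutlin-3. The repeat arrays, which the series record describes as samples hybridised again, were treated as further arrays of the same conditions and were never averaged with the first arrays or counted as extra samples of a first-array group. Each group had 3 arrays except vector with DMSO and flagellin, which had 2 because no array was labelled replicate 1.

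16 comparisons were fixed before the data were examined. In the first arrays these were flagellin against none in each of the 4 line and drug conditions, Nutlin-3 against DMSO in each line, p53i against vector in DMSO, and 4 interactions. The interactions were flagellin by Nutlin-3 in vector, flagellin by line in Nutlin-3, flagellin by Nutlin-3 by line, and Nutlin-3 by line. In the repeat and SB203580 arrays they were flagellin without and with SB203580, SB203580 without and with flagellin, and flagellin by SB203580. No array was shared between groups.

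Tests used limma 3.58.1 in R 4.3.3, with lmFit and eBayes with an intensity trend, and p-values were adjusted over the genes of each comparison by the method of Benjamini and Hochberg. A gene was counted as changed at adjusted p < 0.05. An error after ± in the text is the standard error from limma for a log2 fold change and the standard deviation for a group signal. Gene lists written in advance were tested with camera from limma, with a preset correlation of 0.01 between genes, and adjusted over the 208 tests of 13 lists in 16 comparisons. The same lists were tested with an estimated correlation. The 13 lists were p53 targets, cell cycle genes, NF-kB inflammatory targets, immediate early genes, TLR pathway components, p38 MAPK pathway components, interferon-stimulated genes, estrogen response genes, apoptosis regulators, cholesterol synthesis genes, stress response genes (ATF4 and unfolded protein), antigen presentation genes, and lysosome and autophagy genes. 4 marker lists (leukocyte, fibroblast, basal or mesenchymal epithelial, luminal epithelial) were tested apart from these, as 64 tests. List members were counted past adjusted p over all genes and also adjusted over the list alone. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for tables and figures.

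Genes named in the text were chosen by a rule fixed in advance. It took the 10 largest rises and the 10 largest falls among genes past adjusted p 0.05 whose samples did not overlap between groups (for interactions, past adjusted p only), up to 4 passing members of each list, or up to 2 members with values where fewer than 2 passed, and a fixed set of genes of the p53 and flagellin pathways. Some genes that the rule named were left out of the text.

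Replicate numbers in the titles were the only source of pairing. For each array the deviation from its group mean was correlated with those of the other group of its comparison. In the first arrays the correlations of equal numbers ran from 0.169 to 0.383 for flagellin in vector DMSO, from 0.394 to 0.522 for flagellin in vector Nutlin-3, and from 0.625 to 0.745 for flagellin in p53i DMSO. Replicate number was fitted as a block in an alternative fit and not in the fit the results come from. SB203580 arrays were not paired with repeat arrays, because their equal-number correlations ran from -0.071 to 0.26 without flagellin and from -0.055 to 0.186 with flagellin. The block alternative was nevertheless fitted to them as to the other arrays. Repeat arrays showed no such match with first arrays of the same number (-0.071 to 0.05), so the number before the A was not used to link samples in the fits the results come from. It was used in 1 alternative, named below, which takes arrays of equal number and group as the same RNA.

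Alternatives tried were a block for replicate number, the mean of a gene's probe sets in place of 1 probe set, no intensity trend, no expression filter, log2(signal + 1), log2(signal + 36), quantile normalization, all 35 arrays in a single fit of 10 groups, with the set (first arrays, or repeat and SB203580 arrays) as a covariate and first and repeat arrays of equal number as correlated arrays (consensus correlation 0.124), first arrays as comparators of the SB203580 arrays, and each array left out in turn. Counts without the 2 SB203580 arrays numbered 3, and without all 4 arrays of that fit numbered 3 or 3A, were added after the data were seen. The former left 2 arrays in each SB203580 group, and the latter left 2 arrays in each group of that fit. Where both groups had 3 arrays their labels were exchanged in all 10 distinct ways, and for interactions of groups of 3 the labels were exchanged in both arms together, with 100 splits drawn. A self-test drew simulated arrays from normal distributions with each gene's mean and fitted SD, and added known changes to 200 genes. Values were drawn independently, without the correlations between equal replicate numbers given above, so its rates may not hold for the real arrays. For flagellin in vector DMSO it recovered 56.7% of 2-fold changes, with 10 false among 124 calls, and for flagellin in vector Nutlin-3 59.7%, with 3 false among 132 calls. For flagellin by Nutlin-3 in vector it recovered 38.8% of 2-fold and 80.3% of 4-fold differences, and for SB203580 with flagellin 28.4% and 62.1%.

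The labels did not state whether replicates came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical. MAS5 signals came without a stated background level, so it was not known which dim signals were above background, and a fold from a signal near the floor has no firm lower group.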

Results

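The data were gene expression arrays of MCF-7 cells, an estrogen receptor positive line from a human breast adenocarcinoma. The cells carried either an empty vector or a short hairpin RNA against p53 (p53i). They received Nutlin-3, which frees p53 from MDM2, at 10 µM or DMSO at 0.1% for 45 h, and then flagellin, the bacterial ligand of TLR5, at 500 ng/ml or nothing for 3 h. 8 such groups had 3 arrays each except vector with DMSO and flagellin, which had 2. Further arrays covered vector cells with Nutlin-3 with and without flagellin, 3 arrays each that the series record describes as samples hybridised again (repeat arrays), and the same conditions with the p38 MAPK inhibitor SB203580, 3 arrays each. The number of arrays limited the precision of every comparison.

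Nutlin-3 in vector cells (n = 3 and 3) answered which genes follow p53 when it is released from MDM2. CDKN1A, the cell cycle inhibitor p21, rose 19.9-fold (log2 fold change 4.31 ± 0.33, adjusted p = 6.7e-10), from a signal of 983.7 ± 317.6 to 19370 ± 3948. MDM2, the target through which p53 limits itself, rose 6.54-fold (2.71 ± 0.17, adjusted p = 3.09e-11), and GDF15, a secreted stress cytokine, rose 26.1-fold (4.71 ± 0.21). Cyclin A2 (CCNA2), needed for S phase, fell 25.5-fold (-4.67 ± 0.18, adjusted p = 1.71e-14), and HMMR, a spindle protein, fell 67.9-fold (-6.09 ± 0.28).

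Of 37 p53 targets 34 rose and 1 fell, with the same numbers when adjusted over the list alone (camera adjusted p = 6.99e-26). Death genes were among them, with FAS up 11.3-fold, TNFRSF10B 3.66-fold and BAX 3.27-fold, as were TP53INP1 (19.4-fold) and SPATA18 (23-fold), which act in autophagy and mitochondrial quality control. The largest rises over all genes included the serpin SERPINB5 (84.5-fold, from a signal of 2.655 near the floor), LRRC15 (37.8-fold), the retinoid enzyme ALDH1A3 (34.1-fold) and the cytokine IL18 (23-fold). All 40 cell cycle genes fell, on either adjustment (adjusted p = 5.39e-47). The mitotic genes DLGAP5 (40.9-fold), NCAPH (35-fold), KIF2C (27-fold), NEK2 (25.3-fold) and CDC20 (23.3-fold) were among the largest falls. Among lysosome and autophagy genes 11 of 15 rose and 0 fell (12 and 0 adjusted over the list alone; adjusted p = 4.74e-06), with the regulator TFEB up 3.21-fold and ULK1 up 2.74-fold. Apoptosis regulators rose as a list, with 9 of 23 members higher and 0 lower (9 and 1 over the list alone; adjusted p = 0.0052).

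Immediate early genes were higher in 15 of 23 cases and lower in 0, also over the list alone (adjusted p = 0.000124, adjusted p = 0.222 with an estimated correlation). FOSL1, a partner of JUN, rose 12-fold, and the phosphatases DUSP6 and DUSP4, which switch off MAP kinases, rose 5.46-fold and 4.83-fold. TLR pathway components were called higher (6 of 21 up, 0 down, 4 and 0 over the list alone; adjusted p = 0.0415, adjusted p = 0.291 with an estimated correlation), with the receptor TLR2 up 4.49-fold. TLR5 itself did not pass (1.06 ± 0.65, adjusted p = 0.243). Antigen presentation genes were called higher (7 up and 1 down of 14, 8 and 1 over the list alone; adjusted p = 0.0373, adjusted p = 0.575 with an estimated correlation).

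NF-kB inflammatory targets were not called after Nutlin-3 alone (8 up and 2 down of 33, 8 and 3 over the list alone; adjusted p = 0.144). Within that list LIF rose 3.8-fold, RELB 2.33-fold and the inhibitor NFKBIA 1.76-fold. The chemokine genes CXCL8 (0.65 ± 0.44, adjusted p = 0.289) and CCL20 (0.06 ± 0.36, adjusted p = 0.923) and the cytokine gene TNF (0.14, adjusted p = 0.872) did not pass. PHGDH and ASNS, enzymes of serine and asparagine synthesis, fell 10.6-fold and 4.05-fold. In total 4610 of 14743 genes changed, 2524 higher and 2086 lower, and 42.5% of all genes had samples that did not overlap between the groups, against 10% by chance.

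Nutlin-3 in p53i cells (n = 3 and 3) answered how much of that response remained with p53 knocked down. 12 genes rose and 0 fell, and 7.4% of all genes had samples that did not overlap, against 10% by chance. PHLDA3, a p53 target that restrains AKT, rose 2.76-fold (1.47 ± 0.17, adjusted p = 0.000412), GDF15 2.65-fold, TNFRSF10B 1.79-fold, IER5 1.7-fold and BAX 1.7-fold. CDKN1A (1.36 ± 0.33, adjusted p = 0.383) and MDM2 (0.42 ± 0.17, adjusted p = 1) did not pass. With replicate number as a block CDKN1A did pass (1.357, adjusted p = 0.0101). As a list the p53 targets were higher (9 up and 0 down of 37, 23 and 0 over the list alone; adjusted p = 1.01e-36). Lysosome and autophagy genes were called higher without a single passing member (0 of 15; adjusted p = 0.00192). Cell cycle genes were called lower with 0 of 40 members passing (adjusted p = 1.34e-05, adjusted p = 0.549 with an estimated correlation). Antigen presentation genes were called higher with 0 of 14 passing (adjusted p = 0.00316, adjusted p = 0.394 with an estimated correlation). Interferon-stimulated genes were called only with the block (adjusted p = 0.0793 without it, 0.0373 with it, adjusted p = 0.688 with an estimated correlation).

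The count in p53i cells depended on single arrays. It was 1 without the array labelled p53i Nutlin replicate 1, whose RNA had a high 3' to 5' ratio of ACTB (log2 2.02), 4 without p53i Nutlin replicate 2, 7 without p53i Nutlin replicate 3, 5 without p53i DMSO replicate 2 and 3 without p53i DMSO replicate 3. Without p53i Nutlin replicate 1 the values were GDF15 adjusted p = 0.0584, IER5 0.0584, TNFRSF10B 0.052 and BAX 0.122. GDF15 also lost its call without p53i DMSO replicate 3 (adjusted p = 0.0511), and BAX without p53i DMSO replicate 2 (0.0545), p53i Nutlin replicate 2 (0.191) and p53i DMSO replicate 3 (0.186). PHLDA3 kept its call throughout.

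The interaction of Nutlin-3 and line asked whether the response differed between the lines. MDM2 responded more in vector cells by a log2 difference of 2.29 ± 0.24 (adjusted p = 3.93e-07), CDKN1A by 2.96 ± 0.47 (adjusted p = 8.59e-05), GDF15 by 3.30, TP53INP1 by 3.15 and SERPINB5 by 6.36. CCNA2 (-4.33 ± 0.25, adjusted p = 1.1e-10) and KIF2C (-4.51) responded more negatively in vector cells. So did PHGDH (-3.49). 28 of 37 p53 targets had a larger response in vector and 1 a smaller response (31 and 1 over the list alone; adjusted p = 8.27e-21). All cell cycle calls were in the negative direction, 39 of 40 genes (40 over the list alone; adjusted p = 2.78e-56). Lysosome and autophagy genes (6 up and 0 down of 15, 11 and 0 over the list alone; adjusted p = 4.71e-05) and apoptosis regulators (6 and 0 of 23, 8 and 0 over the list alone; adjusted p = 0.00555) were also called. Immediate early genes were called (9 and 0 of 23, 11 and 0 over the list alone; adjusted p = 0.000507, adjusted p = 0.278 with an estimated correlation), with FOSL1 at 3.34 and DUSP6 at 2.33. TLR2 had a larger response in vector (2.16, adjusted p = 1.16e-05), as did TFEB (1.61). CXCL8 passed too (2.22 ± 0.62, adjusted p = 0.0163), but its p53i Nutlin-3 signals were near the floor (16.99 ± 20.85), and without the array labelled p53i Nutlin replicate 2 its value was 1.83 (adjusted p = 0.0597). In all, 2177 genes had an interaction, 1021 positive and 1156 negative. All 12 genes that rose in p53i cells were among those that rose in vector cells (12 shared, 2.1 expected by chance).

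**Figure D1:**
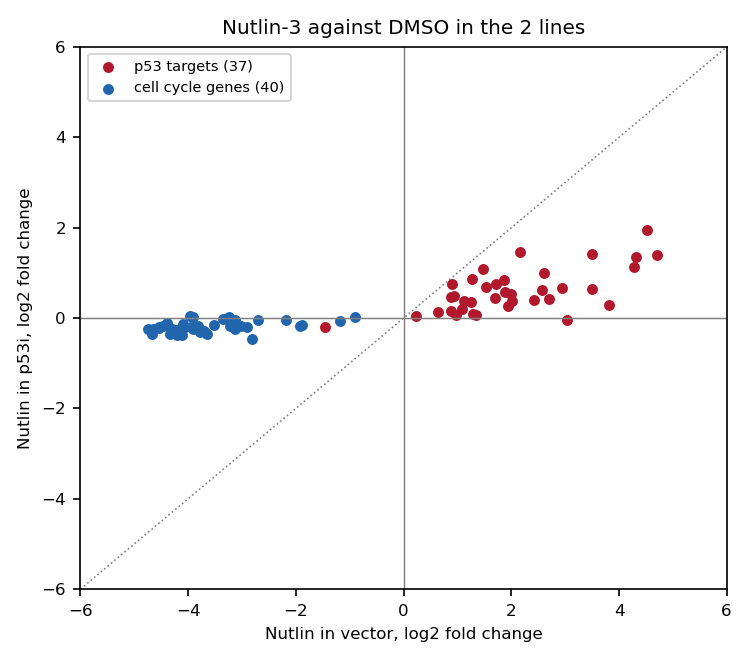
Response to Nutlin-3 of p53 targets and cell cycle genes as log2 fold change in vector cells and in p53i cells, 3 arrays per group. The dotted line marks equal responses.

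The comparison of p53i with vector in DMSO (n = 3 and 3) asked which genes differed between the lines at rest. CDKN1A was 2.41-fold lower in p53i cells (log2 fold change -1.27 ± 0.33, adjusted p = 0.0241), FAS 2.32-fold (adjusted p = 0.00854), SPATA18 4.06-fold, CYFIP2, a p53 target in actin control, 3.5-fold, TNFRSF10B 1.54-fold and BAX 1.4-fold. MDM2 did not pass (0.20 ± 0.17, adjusted p = 0.606). Among 37 p53 targets 10 fell and 1 rose (14 and 2 over the list alone; adjusted p = 2.38e-05, adjusted p = 0.264 with an estimated correlation). The selenium carrier SELENOP was 30.1-fold higher, CLEC3A 27.3-fold and CRISPLD1 25.8-fold, while the retinoic acid hydroxylase CYP26B1 was 20.8-fold and TNFRSF19 19.8-fold lower. TNFSF10, which encodes the death ligand TRAIL, was 5.11-fold higher, the chemokine CXCL12 2.85-fold higher, and stanniocalcin (STC1) 5.7-fold lower. Cholesterol synthesis genes were called lower (1 up and 1 down of 16, 1 and 3 over the list alone; adjusted p = 0.00248, adjusted p = 0.306 with an estimated correlation), with the sterol carrier STARD4 2-fold lower. TLR5 (-0.23 ± 0.65, adjusted p = 0.909), CXCL8 (1.01, adjusted p = 0.217) and CCL20 (0.06, adjusted p = 0.964) did not pass.

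In this resting comparison 820 genes differed, 418 higher and 402 lower in p53i, and 1701 (846 and 855) with replicate number as a block. The count was 541 without the array labelled vector DMSO replicate 1 and 488 without p53i DMSO replicate 3. CDKN1A lost its call without vector DMSO replicate 1 (adjusted p = 0.136) or 3 (0.0566), and without p53i DMSO replicate 1 (0.0566), 2 (0.0714) or 3 (0.065). BAX lost its call without vector DMSO replicate 1 (0.139) or p53i DMSO replicate 1 (0.0593) or 3 (0.133), and FAS without vector DMSO replicate 1 (0.0678). 3 lists were called only with the block: interferon-stimulated genes (adjusted p = 0.0613 without it, 0.0323 with it, adjusted p = 0.677 with an estimated correlation), immediate early genes (0.101 and 0.038, adjusted p = 0.659 with an estimated correlation) and estrogen response genes (0.145 and 0.0482, adjusted p = 0.688 with an estimated correlation).

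Flagellin in vector cells with DMSO (n = 2 with and 3 without) answered what TLR5 stimulation does with p53 at its resting level. CCL20, a chemokine for dendritic cells and lymphocytes, rose 28.5-fold (4.83 ± 0.41, adjusted p = 7.68e-08), from a signal of 5.348 ± 2.928 to 414.8 ± 185.4. The lymphotoxin gene LTB rose 24.4-fold (4.61 ± 0.42), CXCL10, a chemokine for T cells, 17.3-fold (4.11 ± 0.59), and the kinase gene MAP3K8 12.2-fold (3.61 ± 0.37). CXCL8, the neutrophil chemokine, rose 7.46-fold (2.90 ± 0.49, adjusted p = 0.000677) and TNF 7.41-fold (2.89 ± 0.58, adjusted p = 0.00432). Feedback inhibitors of NF-kB rose as well, TNFAIP3 by 8.09-fold (3.02 ± 0.27) and NFKBIA by 4.79-fold (2.26 ± 0.15, adjusted p = 3.49e-09).

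Of 33 NF-kB targets 22 rose and 0 fell (27 and 0 over the list alone; adjusted p = 5.79e-40). S100A8 rose 14.3-fold, LCN2, which binds bacterial siderophores, 12.8-fold, complement factor CFB 16.3-fold and the acute-phase inhibitor SERPINA3 10.8-fold. IGFL1 rose 25.3-fold and the transcription factor MAFF 15.5-fold. Antigen presentation genes rose as a list (8 up and 0 down of 14, 10 and 0 over the list alone; adjusted p = 3.99e-12), with the peptide transporter TAP1 up 4.72-fold and the proteasome subunit PSMB8 up 3.09-fold. Apoptosis regulators were called higher (6 and 1 of 23, 9 and 1 over the list alone; adjusted p = 0.00515), although APAF1, the caspase-9 adaptor, fell 2.99-fold. TLR pathway components were called higher (2 and 0 of 21, 3 and 0 over the list alone; adjusted p = 0.00234, adjusted p = 0.0976 with an estimated correlation), with IRAK2 up 10.1-fold and TLR2 4.77-fold. TLR5 did not pass (-0.76 ± 0.73, adjusted p = 0.768).

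Immediate early genes were called higher with flagellin in vector DMSO (4 and 0 of 23, 6 and 0 over the list alone; adjusted p = 2e-05, adjusted p = 0.171 with an estimated correlation). Stress response genes were called higher (4 and 0 of 18, 6 and 1 over the list alone; adjusted p = 0.000119, adjusted p = 0.108 with an estimated correlation), with CEBPB up 2.09-fold. Interferon-stimulated genes were called higher (4 and 0 of 29; adjusted p = 0.0183, adjusted p = 0.576 with an estimated correlation), and cell cycle genes lower without a passing member (0 of 40; adjusted p = 0.00888, adjusted p = 0.737 with an estimated correlation). p53 targets were not called (5 and 0 of 37, 7 and 0 over the list alone; adjusted p = 0.137). Their median (-0.004) was negative while their mean (0.153) and the test were positive. NINJ1 rose 2.51-fold and TNFRSF10B 1.96-fold, while CDKN1A (1.29 ± 0.37, adjusted p = 0.0576) and MDM2 (-0.08 ± 0.19, adjusted p = 0.939) did not pass. KLHDC7A fell 5.99-fold, the bombesin receptor GRPR 5.47-fold, PRR15L 4.06-fold and the chemokine receptor ACKR3 3.5-fold.

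493 genes changed with flagellin in vector DMSO, 341 higher and 152 lower, and 877 (521 and 356) with replicate number as a block. The count was 223 without the array labelled vector DMSO flagellin replicate 2 and 195 without replicate 3 of that group, which left a single array there. With a single array the group adds nothing to the estimate of spread, which then comes from the other groups alone, so these p-values rest on no replicates in that group. Without replicate 3 CXCL8 (2.43, adjusted p = 0.0526) and TNF (2.04, adjusted p = 0.226) lost their calls. CDKN1A gained a call with the block (1.492, adjusted p = 0.00086) and without the array labelled vector DMSO replicate 1 (1.53, adjusted p = 0.0413). 31% of genes had samples that did not overlap, against 20% by chance.

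Flagellin in vector cells with Nutlin-3 (n = 3 and 3) answered what the same stimulus does after p53 has been active for 45 h. CCL20 rose 129-fold (7.01 ± 0.36, adjusted p = 1.31e-11), to a signal of 1975 ± 751, and CXCL8 38.1-fold (5.25 ± 0.44, adjusted p = 1.27e-08), to 1945 ± 605.8. The survival gene BCL2A1 rose 36.7-fold (5.20 ± 0.53) and TNF 20.1-fold (4.33 ± 0.52, adjusted p = 2.51e-06). TNFAIP3 rose 11.4-fold (3.51 ± 0.25) and NFKBIA 3.98-fold (1.99 ± 0.13).

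Of 33 NF-kB targets 29 rose and 0 fell (32 and 0 over the list alone; adjusted p = 5.71e-43). The cytokine subunit EBI3 (46.6-fold), the GTPase GBP1 (45.2-fold), CCL22 (40.2-fold), CFB (39.6-fold), CXCL10 (26.8-fold), IGFL1 (110-fold) and COXFA4L3 (74.8-fold) rose strongly. All but 1 of 14 antigen presentation genes rose (13 and 0 on either adjustment; adjusted p = 2.9e-18), with PSMB9 up 5.85-fold, PSMB8 5.47-fold, TAP1 3.79-fold and HLA-G 3.44-fold. Interferon-stimulated genes were called higher (10 and 0 of 29, 10 and 1 over the list alone; adjusted p = 1.28e-07, adjusted p = 0.145 with an estimated correlation). The RNA sensors RIGI (10-fold, adjusted p = 1.76e-08) and IFIH1 (9.72-fold) led them. Apoptosis regulators were called higher (10 and 2 of 23, 11 and 2 over the list alone; adjusted p = 1.29e-07), and the death-promoting BCL2L11 (3.04-fold) and PMAIP1 (2.6-fold) and the inhibitor CFLAR (2.45-fold) rose.

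Immediate early genes were called higher with flagellin in vector Nutlin-3 (7 and 2 of 23, 8 and 2 over the list alone; adjusted p = 0.000429, adjusted p = 0.271 with an estimated correlation). PLAUR rose 8.69-fold and ATF3 4.82-fold, but EGR1 fell 3.37-fold (-1.75 ± 0.26, adjusted p = 4.34e-05) and FOS 3.25-fold. TLR pathway components were called higher (4 and 2 of 21, 6 and 3 over the list alone; adjusted p = 0.021, adjusted p = 0.222 with an estimated correlation). IRAK2 rose 27.7-fold and TLR2 2.28-fold, UNC93B1, the chaperone of TLRs, fell 4.15-fold, and TLR5 did not pass (-1.35 ± 0.65, adjusted p = 0.18). Cell cycle genes were called lower, although 27 of 40 members did not pass (0 and 13 of 40, 0 and 19 over the list alone; adjusted p = 0.000401, adjusted p = 0.617 with an estimated correlation), with KIF23, CDC20 and BRCA1 down 2.11-fold, 2.09-fold and 2.07-fold and CCNE2 1.9-fold. Cholesterol synthesis genes were called higher (4 and 1 of 16; adjusted p = 0.0292, adjusted p = 0.532 with an estimated correlation). p53 targets were not called (5 and 3 of 37, also over the list alone; adjusted p = 0.328), with a median of -0.078 and a mean of 0.036. CDKN1A (0.03 ± 0.33, adjusted p = 0.972) and MDM2 (-0.03 ± 0.17, adjusted p = 0.942) did not pass, DRAM1 rose 2.1-fold and NINJ1 1.98-fold.

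2411 genes changed with flagellin in vector Nutlin-3, 897 higher and 1514 lower, and 33.3% of genes had samples that did not overlap, against 10% by chance. ACKR3 fell 5.73-fold, FIGN 4.85-fold, FZD2, a WNT receptor, 4.69-fold and TRIB3 2.17-fold. Of the genes that rose with DMSO 298 also rose with Nutlin-3 (20.7 expected by chance), and of those that fell 129 also fell (15.6 expected).

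Flagellin in p53i cells answered what remains of its effect with p53 knocked down. With DMSO (n = 3 and 3) CCL20 rose 33.5-fold (5.07 ± 0.36, adjusted p = 5.18e-09), SERPINA3 19.6-fold, the cytokine LIF 18.5-fold, IGFL1 18.2-fold, MAFF 14.8-fold and TNF 10.1-fold (adjusted p = 0.000199). CXCL10 rose 8.8-fold, IRAK2 7.65-fold, TNFAIP3 6.77-fold, NFKBIA 3.74-fold, TLR2 3.61-fold and CXCL8 2.75-fold (1.46 ± 0.44, adjusted p = 0.0473). Of 33 NF-kB targets 23 rose and 1 fell (25 and 1 over the list alone; adjusted p = 2.42e-31). Antigen presentation genes (8 and 0 of 14, 12 and 0 over the list alone; adjusted p = 1.46e-11), with TAP1 up 5.7-fold and PSMB9 up 3.08-fold, were called higher, as were apoptosis regulators (8 and 2 of 23, 10 and 3 over the list alone; adjusted p = 0.00236). Immediate early genes (8 and 0 of 23, 10 and 0 over the list alone; adjusted p = 5.84e-09), with KLF4 up 2.48-fold, were also called.

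p53 targets were called higher with flagellin in p53i DMSO (9 and 1 of 37, 10 and 4 over the list alone; adjusted p = 0.0183, adjusted p = 0.576 with an estimated correlation). CDKN1A rose 2.77-fold (1.47 ± 0.33, adjusted p = 0.0068), GDF15 2.54-fold and TNFRSF10B 2.36-fold, and MDM2 did not pass (-0.39, adjusted p = 0.217). PRR15L fell 4.47-fold, the transcription factor KLF15 4.38-fold and SEMA3F 3.61-fold. 968 genes changed, 571 higher and 397 lower, and 1639 (866 and 773) with replicate number as a block. CDKN1A lost its call without the array labelled p53i DMSO flagellin replicate 1 (1.03, adjusted p = 0.0575). CXCL8 lost its call without p53i DMSO replicate 1 (adjusted p = 0.0556), 2 (0.202) or 3 (0.0899) and without p53i DMSO flagellin replicate 1 (0.165) or 3 (0.166).

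With Nutlin-3 (n = 3 and 3) flagellin in p53i cells raised IGFL1 45.1-fold, CCL20 32.6-fold (5.03 ± 0.36, adjusted p = 4.67e-09), SERPINA3 30.5-fold, CFB 23.7-fold, LTB 11.9-fold and BCL2A1 10.9-fold. CXCL8 rose 10.2-fold (3.35 ± 0.44, adjusted p = 1.81e-05), TNF 5-fold (2.32 ± 0.52, adjusted p = 0.00554), TNFAIP3 6.6-fold and NFKBIA 3.34-fold. Without flagellin the CXCL8 signals were 41, 3.3 and 6.7, the last ones near the floor, against 73, 35.1 and 61 in p53i DMSO. With flagellin they were 256.3, 125.7 and 278.4, against 214.9, 99.5 and 208 in p53i DMSO. The larger CXCL8 fold with Nutlin-3 thus came mainly from the signals without flagellin. NF-kB targets (23 and 0 of 33, 26 and 0 over the list alone; adjusted p = 1.01e-31), antigen presentation genes (11 and 0 of 14, 13 and 0 over the list alone; adjusted p = 3.05e-12) and apoptosis regulators (9 and 1 of 23, 9 and 2 over the list alone; adjusted p = 0.001) were called higher. So were immediate early genes (6 and 0 of 23, 8 and 0 over the list alone; adjusted p = 2.6e-06, adjusted p = 0.125 with an estimated correlation) and interferon-stimulated genes (5 and 0 of 29, 7 and 0 over the list alone; adjusted p = 0.000112, adjusted p = 0.314 with an estimated correlation). Cell cycle genes were called lower (0 and 2 of 40, 0 and 1 over the list alone; adjusted p = 4.24e-05, adjusted p = 0.575 with an estimated correlation). p53 targets were not called (7 and 2 of 37, 9 and 4 over the list alone; adjusted p = 0.159), with a median of -0.015 and a mean of 0.101.

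In p53i cells with Nutlin-3 flagellin also raised CDKN1A 2.33-fold (1.22 ± 0.33, adjusted p = 0.0214) and GDF15 2.25-fold, and lowered the receptor EDA2R 3.55-fold (adjusted p = 0.0116), JAKMIP3 4.59-fold and PRR15L 4.31-fold. 1245 genes changed, 701 higher and 544 lower, and 1996 (1024 and 972) with replicate number as a block. CDKN1A lost its call without the array labelled p53i Nutlin flagellin replicate 1 (0.92, adjusted p = 0.133), p53i Nutlin replicate 2 (1.21, adjusted p = 0.0658) or p53i Nutlin replicate 3 (0.89, adjusted p = 0.142), and EDA2R without p53i Nutlin replicate 2 (-1.74, adjusted p = 0.0503). The arrays labelled replicate 1 in the p53i Nutlin groups had the highest 3' to 5' ratios of ACTB among first arrays (log2 2.02 without and 2.2 with flagellin). Of the genes that rose with DMSO 495 also rose with Nutlin-3 (27.1 expected by chance), and of those that fell 291 also fell (14.6 expected). Between the lines with Nutlin-3, 467 rising genes (42.7 expected) and 408 falling genes (55.9 expected) were shared.

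The interaction of flagellin and Nutlin-3 in vector cells asked whether active p53 changes the flagellin response. VASH2, a tubulin carboxypeptidase, responded more with Nutlin-3 by a log2 difference of 3.43 ± 0.31 (adjusted p = 2.37e-06), the heparan sulfate enzyme HS3ST3B1 by 4.01, BCL2A1 by 4.65 ± 0.79 (adjusted p = 0.00718), CCL22 by 4.45 ± 0.89 (adjusted p = 0.0191) and IFIH1 by 2.11. EGR1 responded more negatively (-2.15 ± 0.40, adjusted p = 0.0105). BCL2A1 went from 43.66 ± 0.2468 with DMSO and flagellin to 1264 ± 633.5 with Nutlin-3 and flagellin. Flagellin also raised BCL2A1 4.31-fold in p53i cells with DMSO (adjusted p = 0.0152). BCL2A1 did not pass for flagellin by line with Nutlin-3 (1.75 ± 0.75, adjusted p = 0.472). It also did not pass for flagellin by Nutlin-3 by line (3.32 ± 1.09, adjusted p = 0.818). CCL20 (2.17 ± 0.54, adjusted p = 0.0882), CXCL8 (2.35 ± 0.66, adjusted p = 0.146), TNF (1.44 ± 0.78, adjusted p = 0.728), TNFAIP3 (0.50 ± 0.37, adjusted p = 0.84) and NFKBIA (-0.27 ± 0.20, adjusted p = 0.842) did not pass. With replicate number as a block CXCL8 (2.19, adjusted p = 0.0228) and CCL20 (2.163, adjusted p = 0.0244) passed.

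As lists, NF-kB targets (3 and 0 of 33, 7 and 1 over the list alone; adjusted p = 7.66e-11, adjusted p = 0.0837 with an estimated correlation) and interferon-stimulated genes (2 and 0 of 29, 5 and 0 over the list alone; adjusted p = 8.27e-07, adjusted p = 0.18 with an estimated correlation) responded more with Nutlin-3 in vector. Antigen presentation genes (1 and 0 of 14, 6 and 0 over the list alone; adjusted p = 1.31e-09) and apoptosis regulators (2 and 0 of 23, 5 and 0 over the list alone; adjusted p = 7.9e-06) were called in the same direction. Cell cycle genes were called only with the block (adjusted p = 0.0613 without it, 0.00949 with it, adjusted p = 0.84 with an estimated correlation). Cholesterol synthesis genes were called only without it (adjusted p = 0.031 and 0.0746, adjusted p = 0.532 with an estimated correlation). 73 genes had this interaction, 55 positive and 18 negative, and 241 (126 and 115) with the block. The count was 10 without the array labelled vector DMSO flagellin replicate 2, 28 without replicate 3 of that group, each time with a single array left there and no replicate basis in it, and 48 without vector Nutlin flagellin replicate 1. Without vector DMSO flagellin replicate 2 the adjusted p was 0.0623 for BCL2A1, 0.251 for CCL22, 0.0742 for IFIH1 and 0.081 for EGR1. Without replicate 3 it was 0.0503 for IFIH1 and 0.0567 for EGR1, and without vector Nutlin flagellin replicate 1 it was 0.0644 for CCL22.

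The interaction of flagellin and line with Nutlin-3 asked whether the flagellin response was larger in vector than in p53i cells. The lines also differed at rest in 820 genes. Loss of p53 therefore cannot be told apart here from other differences between the lines. VASH2 (3.33 ± 0.29, adjusted p = 1.36e-06), HS3ST3B1 (3.29, adjusted p = 0.00481), IFIH1 (2.34 ± 0.36, adjusted p = 0.00181) and PLAUR (1.99, adjusted p = 0.007) responded more in vector cells, and EGR1 more negatively (-2.23 ± 0.37, adjusted p = 0.00368). CCL20 (1.98 ± 0.51, adjusted p = 0.0881), CXCL8 (1.90 ± 0.62, adjusted p = 0.241), TNF (2.01 ± 0.74, adjusted p = 0.348), TNFAIP3 (0.79, adjusted p = 0.496) and NFKBIA (0.25, adjusted p = 0.793) did not pass. With the block CXCL8 (1.9, adjusted p = 0.0309) and CCL20 (1.981, adjusted p = 0.0229) passed. NF-kB targets (2 and 0 of 33, 9 and 0 over the list alone; adjusted p = 9.22e-16) and apoptosis regulators (1 and 0 of 23, 4 and 0 over the list alone; adjusted p = 1e-04) were called higher in vector. Interferon-stimulated genes (3 and 0 of 29, 4 and 0 over the list alone; adjusted p = 0.000832, adjusted p = 0.423 with an estimated correlation) and antigen presentation genes (0 and 0 of 14, 5 and 0 over the list alone; adjusted p = 6.45e-08, adjusted p = 0.0672 with an estimated correlation) were called too. 89 genes had this interaction, 60 positive and 29 negative, and 313 (156 and 157) with the block. The count was 59 without the array labelled vector Nutlin flagellin replicate 2, 58 without replicate 3 of that group and 46 without p53i Nutlin flagellin replicate 2.

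The interaction of all 3 factors asked whether the effect of Nutlin-3 on the flagellin response differed between the lines. 3 genes passed, all positive, and 10 (7 and 3) with the block. They were VASH2 (3.30 ± 0.42, adjusted p = 0.00125), the ubiquitin ligase TRIM25 (1.62 ± 0.25, adjusted p = 0.00849) and the microtubule protein DPYSL2 (1.502 ± 0.22, adjusted p = 0.00676). TRIM25 lost its call without the array labelled vector DMSO flagellin replicate 2 (1.45, adjusted p = 0.0868), again with a single array left in that group. CCL20 (2.21 ± 0.75, adjusted p = 0.859) and CXCL8 (0.46 ± 0.90, adjusted p = 0.999) did not pass. The CXCL8 value rested in part on p53i Nutlin-3 signals near the floor. Apoptosis regulators were called (0 of 23 passing, 1 and 0 over the list alone; adjusted p = 0.000401). NF-kB targets (0 of 33; adjusted p = 4.05e-07, adjusted p = 0.197 with an estimated correlation), antigen presentation genes (0 of 14; adjusted p = 3.53e-06, adjusted p = 0.125 with an estimated correlation) and interferon-stimulated genes (0 of 29, 1 and 0 over the list alone; adjusted p = 0.00449, adjusted p = 0.532 with an estimated correlation) were called as well.

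**Figure D2:**
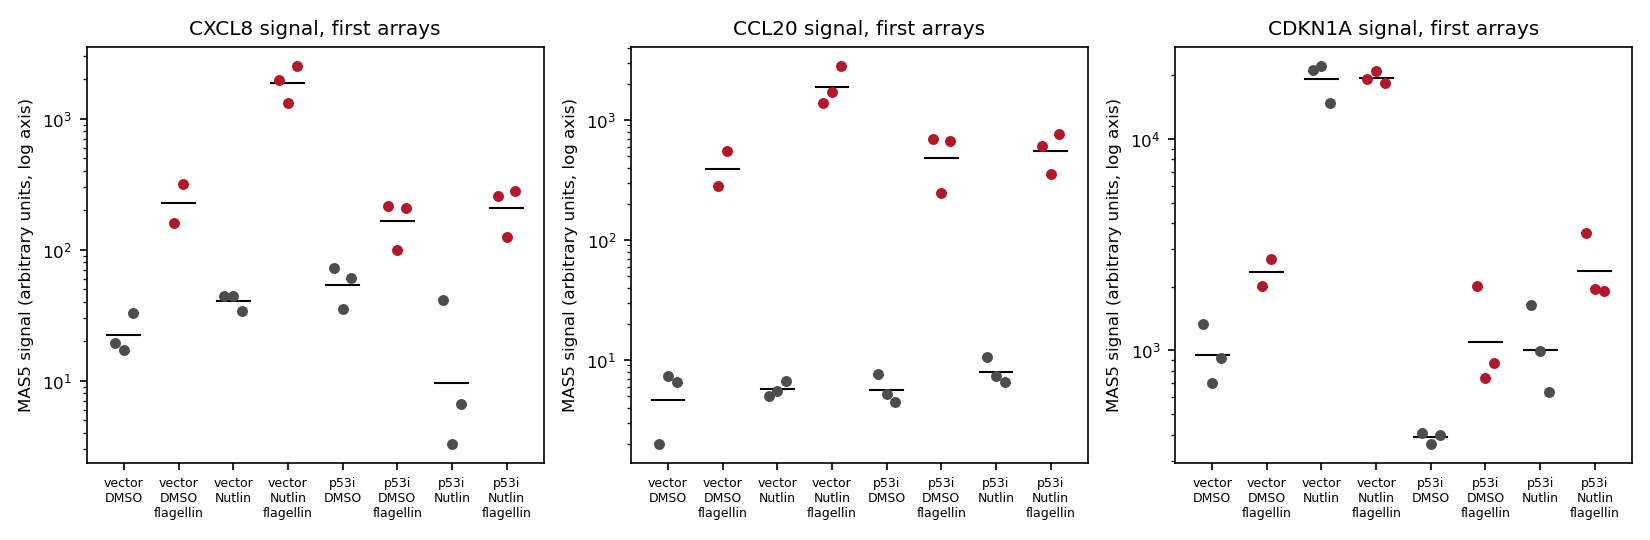
MAS5 signals of CXCL8, CCL20 and CDKN1A on each first array, on a log axis. Points are arrays, red with flagellin and grey without, and lines are geometric means of 2 or 3 arrays.

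**Figure D3:**
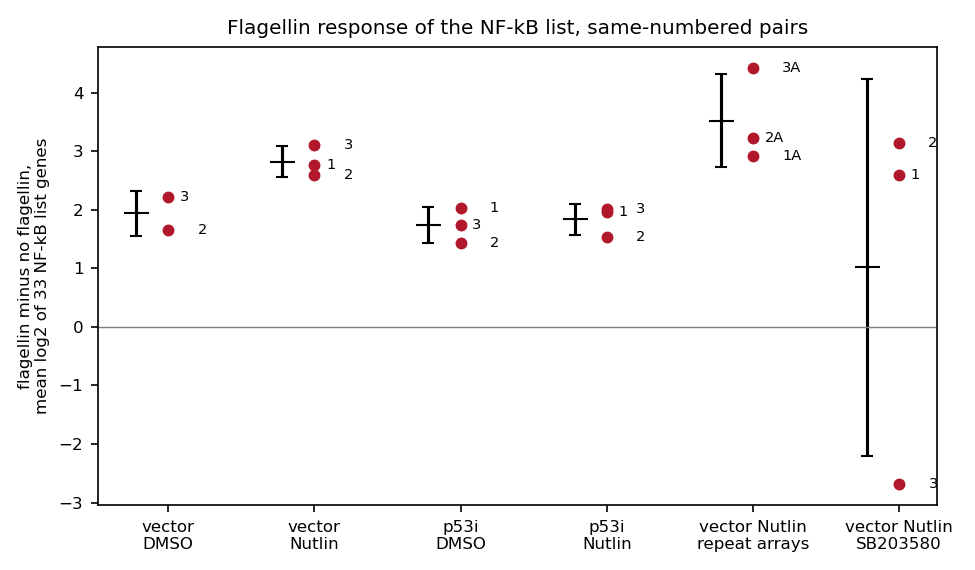
Mean log2 difference of 33 NF-kB targets between flagellin and no flagellin for each pair of arrays with the same replicate number. The dash and bar at the left of each group are mean and SD.

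The repeat arrays of vector cells with Nutlin-3 (n = 3 and 3) asked whether the flagellin response appears on the arrays labelled as repeats. C2CD4A rose 44.5-fold, CCL22 31.7-fold and BPGM, an enzyme of red cell glycolysis, 6.87-fold (adjusted p = 0.0365 each), and these 3 were the only genes that passed. With replicate number as a block 0 genes passed limma (adjusted p = 0.0577 for each of the 3), against 1383 at unadjusted p < 0.05 without it. Leaving out any single array of the 6 also gave 0, with adjusted p from 0.0566 to 0.351 for these genes. Spread in all of these fits came from the repeat and SB203580 arrays together. It thus included the 2 SB203580 arrays numbered 3, which went against their labels (below). The low counts therefore do not measure the repeat arrays alone. CXCL8 (8.37 ± 1.504, adjusted p = 0.121), CCL20 (8.11 ± 2.13, adjusted p = 0.188), TNF (5.57 ± 1.70, adjusted p = 0.257), TNFAIP3 (4.44 ± 1.14, adjusted p = 0.176) and NFKBIA (2.40 ± 0.79, adjusted p = 0.304) had large positive values with large errors. NF-kB targets were called higher as a list (0 of 33 past the adjustment over all genes, 31 and 0 over the list alone; adjusted p = 3.33e-37, adjusted p = 0.0963 with an estimated correlation). So were antigen presentation genes (0 of 15, 8 and 0 over the list alone; adjusted p = 4.48e-11, adjusted p = 0.2 with an estimated correlation). Of 887 genes that rose on the first arrays and were measured on both sets, 868 (97.9%) had the same sign here, as had 1467 of 1512 (97%) that fell. If the repeat arrays hold the same RNA, which was not settled, this shows repeated measurement and not further samples. Without all 4 arrays numbered 3 or 3A, a choice made after seeing the data, 1674 genes changed (825 higher and 849 lower), with CCL20 up 167-fold (adjusted p = 1.65e-07) and CXCL8 up 147-fold (adjusted p = 1.27e-06). Without flagellin CXCL8 was 1.4 and 5.5 on arrays 1A and 2A, near the floor, against 44.2, 44.3 and 33.8 on the first arrays. With flagellin it was 1416.3 and 2296.4, against 1985.4, 1319.9 and 2529.4. The larger CXCL8 fold than on the first arrays thus came mainly from the signals without flagellin. CCL20 without flagellin was 3.2 and 4.4, also near the floor. RNA of the 3A arrays (log2 ACTB ratios 1.8 and 2.07) and of the array labelled flagellin 1A (1.85) had high 3' to 5' ratios.

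Flagellin in the presence of SB203580 (n = 3 and 3) asked whether the response persists when p38 is inhibited. CCL20 (2.74 ± 2.13), CXCL8 (2.65 ± 1.504), TNFAIP3 (1.84 ± 1.14) and NFKBIA (0.87 ± 0.79) did not pass (adjusted p = 1 each). limma called 0 genes, while 2.5% of 14315 genes had an unadjusted p < 0.05. The arrays numbered 3 in these groups went against their labels. CCL20 was 1604.6 on the array labelled no flagellin and 2.8 on the array labelled flagellin, and CDKN1A on these was 2566 and 795. Without these 2 arrays, chosen after seeing the data, 277 genes changed (252 higher and 25 lower), with CCL20 up 201-fold (adjusted p = 0.000181), CXCL8 50.3-fold (adjusted p = 0.01), TNF 32.6-fold (adjusted p = 0.0054), TNFAIP3 21.8-fold and NFKBIA 6.58-fold (adjusted p = 2.57e-05). Without all 4 arrays numbered 3 or 3A the count was 794 (592 and 202), and 27 of 33 NF-kB targets rose and 0 fell (adjusted p = 9.06e-32, adjusted p = 0.0712 with an estimated correlation). On SB203580 arrays 1 and 2 without flagellin CCL20 was 3.2 and 1.7, near the floor, and CXCL8 was 44.7 and 13.8. Leaving out only the array labelled SB203580 replicate 3 gave 5 genes, and leaving out only SB203580 flagellin replicate 3 gave 47. The array labelled SB203580 flagellin replicate 2 had the highest ACTB ratio of all arrays (log2 2.34).

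Direct comparisons of SB203580 with the repeat arrays (n = 3 and 3 each) asked what p38 inhibition changes. Without flagellin CXCL8 (2.70 ± 1.504), CCL20 (2.04 ± 2.13), CDKN1A (-0.93 ± 1.19) and MDM2 (-0.66 ± 0.84) did not pass (adjusted p = 0.985 each), and limma called 0 genes, against 377 at unadjusted p < 0.05. With flagellin CCL20 (-3.33 ± 2.13, adjusted p = 0.758), CXCL8 (-3.02 ± 1.504, adjusted p = 0.713), TNF (-2.61 ± 1.70, adjusted p = 0.762), TNFAIP3 (-1.09, adjusted p = 0.843), NFKBIA (-0.76, adjusted p = 0.843) and CDKN1A (-1.34 ± 1.19, adjusted p = 0.804) did not pass either, with 0 genes called against 1004 at unadjusted p < 0.05. In the interaction of flagellin and SB203580 CXCL8 (-5.72 ± 2.13), CCL20 (-5.37 ± 3.02), TNFAIP3 (-2.60) and NFKBIA (-1.53) did not pass (adjusted p = 1 each), with 0 genes called against 390. First arrays as comparators gave 15 genes for SB203580 with flagellin.

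List tests were called in these comparisons without a single passing member. p53 targets were called lower with SB203580 without flagellin (0 of 37 passing; adjusted p = 0.00333, adjusted p = 0.777 with an estimated correlation) and with it (0 of 37; adjusted p = 1.06e-07, adjusted p = 0.575 with an estimated correlation). Cell cycle genes were called higher without flagellin (0 of 40; adjusted p = 6.86e-08, adjusted p = 0.617 with an estimated correlation) and with it (0 of 40; adjusted p = 9.02e-05, adjusted p = 0.737 with an estimated correlation). NF-kB targets were called higher without flagellin (0 of 33; adjusted p = 1.81e-06, adjusted p = 0.576 with an estimated correlation), lower with it (0 of 33; adjusted p = 3.52e-12, adjusted p = 0.4 with an estimated correlation) and negative in the interaction (0 of 33; adjusted p = 1.83e-23, adjusted p = 0.197 with an estimated correlation). Immediate early genes were called higher without flagellin (0 of 23; adjusted p = 0.0486, adjusted p = 0.632 with an estimated correlation).

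These list calls changed when the doubted arrays were left out, a choice made after seeing the data. For SB203580 without flagellin, leaving out the 2 SB203580 arrays numbered 3 turned the direction of p53 targets to higher (adjusted p = 0.134) and of cell cycle genes to lower (adjusted p = 0.341), and NF-kB targets were no longer called (adjusted p = 0.324). Leaving out all 4 arrays numbered 3 or 3A called p53 targets higher there (0 of 37 passing; adjusted p = 0.0297, adjusted p = 0.813 with an estimated correlation) and cell cycle genes lower (0 of 40 passing, 35 of 40 negative; adjusted p = 3.16e-05, adjusted p = 0.6 with an estimated correlation), and NF-kB targets were not called (adjusted p = 0.721). Immediate early genes stayed higher there, with 22 of 23 members positive without the 2 arrays (0 passing; adjusted p = 7.39e-06, adjusted p = 0.0457 with an estimated correlation). Without the 4 arrays 20 of 23 were positive (1 passing; adjusted p = 3.26e-06, adjusted p = 0.0712 with an estimated correlation). For SB203580 with flagellin, p53 targets were not called without the 2 arrays (adjusted p = 0.592) or without the 4 (adjusted p = 0.79). Cell cycle genes there were not called without the 2 (adjusted p = 0.286) and were called lower without the 4 (adjusted p = 0.00668, adjusted p = 0.798 with an estimated correlation).

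Without all 4 arrays numbered 3 or 3A, SB203580 without flagellin changed 16 genes, 8 higher and 8 lower. This choice, made after seeing the data, left 2 arrays per group. It also dropped the 3A pair, which had the largest flagellin response of the NF-kB list. The collagen receptor subunit ITGA2 (2.3-fold), PHLDA1 (2.31-fold), EGR1 (2.1-fold) and CD44 (1.75-fold) rose, and the xenobiotic enzymes CYP1A1 (11.2-fold) and CYP1B1 (2.1-fold), the estrogen receptor gene ESR1 (2.11-fold) and GBP1 (4.06-fold) fell. With flagellin 245 genes changed, 168 higher and 77 lower. VIM rose 5.94-fold and EGR1 4.65-fold (adjusted p = 6.12e-06), and CCL22 (12-fold, adjusted p = 0.00704), CXCL10 (4.11-fold), S100A8 (3.37-fold) and TET2 (3.18-fold, adjusted p = 6.29e-05) fell. CXCL8 (-0.04 ± 0.51, adjusted p = 0.982), CCL20 (0.10 ± 0.42, adjusted p = 0.935) and TNF (0.09 ± 0.46, adjusted p = 0.949) did not pass. NF-kB targets were not called (0 and 1 of 33; adjusted p = 0.141), nor were they in the interaction (adjusted p = 0.118). Antigen presentation genes were called lower with flagellin (0 and 2 of 15; adjusted p = 0.00139, adjusted p = 0.106 with an estimated correlation) and in the interaction (0 of 15 passing, 12 negative; adjusted p = 0.000716, adjusted p = 0.106 with an estimated correlation). Apoptosis regulators (0 of 23 passing; adjusted p = 0.0211, adjusted p = 0.213 with an estimated correlation) and cholesterol synthesis genes (0 of 16 passing; adjusted p = 0.0291, adjusted p = 0.649 with an estimated correlation) were called negative in the interaction. 3 genes had an interaction of flagellin and SB203580, all negative: IGFL1 (-1.68, adjusted p = 0.026), LIF-AS2 (-1.47) and TET2 (-1.36, adjusted p = 0.0312). With only the 2 SB203580 arrays numbered 3 left out, 2, 8 and 0 genes changed in the 3 comparisons. Of the genes named in this paragraph only ITGA2 and ESR1 then kept their call without flagellin. With flagellin only TET2 did (adjusted p = 0.0359), and VIM, EGR1, CXCL10, S100A8 and CCL22 (adjusted p = 0.1) lost theirs. NF-kB targets were then still called lower with flagellin (0 of 33 passing, median -0.308; adjusted p = 0.000438, adjusted p = 0.548 with an estimated correlation) and in the interaction (0 of 33 passing; adjusted p = 4.28e-05, adjusted p = 0.475 with an estimated correlation). CXCL8 (-1.22 ± 0.89, adjusted p = 0.614) and CCL20 (-0.79 ± 0.70, adjusted p = 0.679) did not pass with flagellin in that setting.

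**Figure D4:**
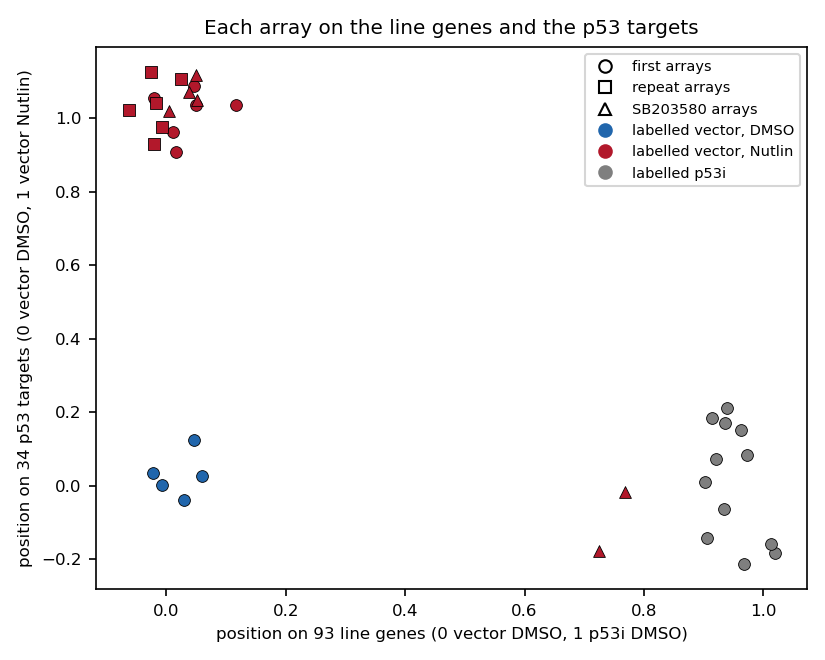
Position of each array between vector DMSO (0) and p53i DMSO (1) on 93 genes that differ between the lines, and between vector DMSO (0) and vector Nutlin-3 (1) on 34 p53 targets. The 93 genes were picked on the first arrays. Circles are first arrays, squares repeat arrays and triangles SB203580 arrays, coloured by label.

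Of 208 list tests 95 were called and 28 of these held with an estimated correlation. They were NF-kB targets, antigen presentation genes and apoptosis regulators in all 4 flagellin comparisons of first arrays, and immediate early genes with flagellin in p53i DMSO. For Nutlin-3 in vector and for Nutlin-3 by line they were p53 targets, cell cycle genes, lysosome and autophagy genes and apoptosis regulators, and for Nutlin-3 in p53i the p53 targets and the lysosome and autophagy genes. For the flagellin interactions they were antigen presentation genes and apoptosis regulators by Nutlin-3 in vector, NF-kB targets and apoptosis regulators by line, and apoptosis regulators for all 3 factors.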

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

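The interactions and their list tests came from the comparisons fixed in advance. The tests of array scaling on the 3A arrays and of dim signals were written before their results were seen. The remaining tests here were chosen after the result was seen.

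Arrays numbered 3A stood out among the 6 arrays of vector Nutlin-3 flagellin, first and repeat together. 3A was the highest array for CXCL8 (21000), CCL20 (13700), TNF (4100) and TNFAIP3 (7730) and the lowest for CCL22 (225), each with a wide gap to the other 5. BPGM was highest on first array 1 (1470). Without flagellin TNFAIP3 was lowest on 3A (125). 16 sets of 6 values were looked at in this way. An array was taken to stand out when the gap to its nearest value was a large enough share of the range of the set. The cut-off is meant to pass about 1 of 20 such sets by chance, a rate that was not checked on these data.

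Genes whose flagellin response differed with Nutlin-3 in vector came to 73, picked out because an effect differed between groups. Their log2 differences were 4.654 for BCL2A1, 4.453 for CCL22, 4.011 for HS3ST3B1, 3.433 for VASH2, 2.106 for IFIH1, 2.103 for TNFAIP2, 1.741 for PLAUR, 1.429 for BCL2L11, 1.395 for the mitochondrial dismutase SOD2, 1.289 for ISG20 and -2.15 for EGR1. Between the lines with Nutlin-3 the difference held for 89 genes, with 3.334 for VASH2, 3.285 for HS3ST3B1, 3.072 for COXFA4L3, 2.504 for the cytokine IL6, 2.339 for IFIH1, 1.987 for PLAUR, 1.917 for RIGI, 1.333 for BCL2L11, 1.193 for ISG20, 1.137 for DUSP5, -2.234 for EGR1 and -1.012 for TRIB3. For all 3 factors it was 3 genes, VASH2 (3.303), TRIM25 (1.621) and DPYSL2 (1.502).

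The response to Nutlin-3 differed between the lines for 2177 genes, picked out for the same reason. Log2 differences were 6.357 for SERPINB5, 3.339 for FOSL1, 3.302 for GDF15, 3.149 for TP53INP1, 2.957 for CDKN1A, 2.33 for DUSP6, 2.292 for MDM2, 2.224 for CXCL8, 2.163 for TLR2 and 1.605 for TFEB. They were -4.505 for KIF2C, -4.329 for CCNA2 and -3.491 for PHGDH.

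The 2 SB203580 arrays numbered 3 had low p53 targets (positions of at most -0.018 between DMSO at 0 and Nutlin-3 at 1) and a reversed flagellin response. RNA of the p53 shRNA line on these arrays may account for this, since they lay at 0.725 and 0.769 on the genes that separate the lines, where the 10 other repeat and SB203580 arrays reached at most 0.052. They fell short of every p53i first array on those genes (0.903 or higher). Those genes were picked on the first arrays, whose DMSO groups also set 0 and 1. Arrays not used for the pick may lie lower for this reason alone, so the shortfall decides nothing. The p53 target positions of the 2 arrays (-0.018 and -0.178) lay within those of p53i DMSO arrays with and without flagellin (-0.214 to 0.01). They lay below those of p53i Nutlin-3 arrays (0.074 to 0.213). An action of SB203580 was excluded, since the 4 other SB203580 arrays lay at 1.019 or higher on the p53 targets. Exchanged flagellin labels remain open, since the mean log2 difference of -2.686 for NF-kB targets, array labelled flagellin minus array labelled without, is the observation itself and no separate test of it.

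The larger flagellin response on the 3A arrays (4.424 for the NF-kB list) was not due to array scaling, as its excess over the 5 other vector Nutlin-3 pairs was 1.502 before and 1.486 after quantile normalization. The first pair numbered 3 had 3.108, a gap of 1.316. This gap cannot settle whether the 3A arrays measured the RNA of the first arrays numbered 3 again. That first pair is among the 5 pairs that 3A exceeded, and no repeat array matched its own number (correlations -0.071 to 0.05). The cause of the larger response on the 3A arrays remains open.

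The larger flagellin response of the NF-kB list in vector cells with Nutlin-3 was not due to dim signals alone. The 11 members bright on every first array still had a median difference between lines of 0.705. This was below the median of the whole list (1.048), so a part from dim signals stays open. The difference with Nutlin-3 within vector cells was not looked at on bright members. Array scaling was excluded for the difference between lines (1.026 after quantile normalization, 1.048 before). On the list mean Nutlin-3 moved the flagellin response of p53i cells by 0.095 (SE 0.23), against 0.885 (SE 0.314) in vector cells. These shifts were just over 2 SE apart when replicate number is ignored. The margin is too thin to exclude an action of Nutlin-3 without p53. In p53i cells 12 genes still rose with Nutlin-3, p53 targets such as GDF15 among them, so p53 was not absent there. The lines also differed at rest in 820 genes. The shifts therefore show a larger change in vector cells but cannot tell its cause. Within replicate numbers the shifts were 0.93 and 0.894 in vector (2 pairs) and -0.079, 0.101 and 0.263 in p53i. The list in the interaction of all 3 factors lost its call with an estimated correlation (adjusted p = 0.197).

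Whether a random division of the arrays would do as well could not be judged where 3 arrays were compared with 3, because 10 splits are too few for a share under 0.05. As many genes as with the real labels were found in 1 of 10 splits for flagellin in vector Nutlin-3 (2411, highest other 1), in p53i DMSO (968, highest other 0) and in p53i Nutlin-3 (1245, highest other 0). The same held for Nutlin-3 in vector (4610) and in p53i (12), p53i against vector (820) and flagellin on the repeat arrays (3), each with 0 as the highest other. With SB203580 the real counts were 0, so all 10 splits had as many, with 104 as the highest other for flagellin and 0 for the inhibitor without or with flagellin.

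For interactions, labels were mixed in both arms together, in 100 drawn splits. At least 89 genes came from 16 of 100 splits for flagellin by line (highest other 3231), and at least 2177 from 10 of 100 for Nutlin-3 by line (highest other 3336). A split that mostly keeps the labels in 1 arm and turns them in the other makes a difference of the treatment effect itself, and 9 of the 15 other splits that reached 89 were of this kind, as were 4 of the 9 that reached 2177. The remaining ones were not, but they could still keep more labels in 1 arm than in the other. Such a split also carries part of the treatment effect. These splits therefore cannot tell whether a random division of the arrays would give as many genes. For flagellin by SB203580 the real count was 0, so all 100 splits had as many, with 416 as the highest other. When whole pairs were exchanged, 1 of 10 splits reached the real count for flagellin by line and for Nutlin-3 by line, with 0 as the highest other. Each of those other splits put vector and p53i arrays into the same group, so differences between the lines enlarged the spread. Besides, 10 splits are too few for a share under 0.05. These exchanges therefore cannot tell either.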

How the results depend on the processing

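Settings were chosen in advance except the counts without arrays numbered 3 or 3A, which were chosen after the result was seen. Each setting below is compared with the fit of the report, and the cause of a shift was not tested unless stated.

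Replicate number as a block gave 877 genes for flagellin in vector DMSO, 1639 in p53i DMSO and 1996 in p53i Nutlin-3, and 1701 for p53i against vector. It gave 241 for flagellin by Nutlin-3 in vector, 313 for flagellin by line, 10 for all 3 factors and 0 for flagellin on the repeat arrays. Of 271 gene results 262 kept their label, 6 became stronger and 3 weaker. List calls numbered 98 against 95. Besides the calls printed in the report, cholesterol synthesis genes with flagellin in p53i DMSO lost theirs (adjusted p = 0.0415 without the block, 0.0566 with it, adjusted p = 0.549 with an estimated correlation), as did immediate early genes with SB203580 without flagellin (0.0486 and 0.0712, adjusted p = 0.632 with an estimated correlation). Immediate early genes with flagellin and SB203580 gained a call (0.0687 and 0.047, adjusted p = 0.662 with an estimated correlation). The block changed no other call.

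The mean of a gene's probe sets moved counts down, except on the repeat arrays. The moved counts were 293 for flagellin in vector DMSO, 1604 in vector Nutlin-3, 602 in p53i DMSO and 776 in p53i Nutlin-3. Nutlin-3 in p53i gave 6 and p53i against vector 512. The interactions gave 35 (flagellin by Nutlin-3), 54 (flagellin by line) and 1 (all 3 factors), and the repeat arrays 5. In this setting SC5D, a sterol desaturase, changed sign with Nutlin-3 in vector (-0.027, adjusted p = 0.957, against 0.798 in the report's fit), the only reversal among all gene results. 38 gene results became weaker and 2 stronger.

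All 35 arrays in a single fit pooled the spread of both sets, so the wide spread of the SB203580 and 3A arrays entered every test. Counts were 67 for flagellin in vector DMSO, 195 in p53i DMSO, 387 in p53i Nutlin-3, 0 for Nutlin-3 in p53i and 172 for p53i against vector. Interactions gave 3 (flagellin by Nutlin-3), 4 (flagellin by line), 0 (all 3 factors) and 125 (Nutlin-3 by line). Flagellin in vector Nutlin-3 gave 1937, from first and repeat arrays together, so this number stands for both of those comparisons and is not a count on the repeat arrays alone. SB203580 was likewise set against first and repeat arrays together. Flagellin with SB203580 gave 1, SB203580 2 without and 409 with flagellin, and their interaction 1. 112 gene results became weaker and 5 stronger.

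Without an intensity trend Nutlin-3 in p53i gave 3 genes, flagellin by Nutlin-3 in vector 45 and the repeat arrays 0. With log2(signal + 1) the repeat arrays gave 0, with quantile normalization 5, and with log2(signal + 36) the interaction of all 3 factors gave 5. Dropping the filter moved no count by more than 1.5-fold. First arrays as comparators gave 15 genes for SB203580 with flagellin. The correlation estimated per list left 28 of 95 list calls.

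Without the 2 SB203580 arrays numbered 3, flagellin with SB203580 gave 277 genes, SB203580 2 without and 8 with flagellin. Without all 4 arrays numbered 3 or 3A, flagellin gave 1674 on the repeat arrays and 794 with SB203580, SB203580 gave 16 without and 245 with flagellin, and their interaction 3.

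Leaving out each array in turn gave 195 to 390 genes for flagellin in vector DMSO, 1879 to 1993 in vector Nutlin-3, 650 to 798 in p53i DMSO and 885 to 1012 in p53i Nutlin-3. Nutlin-3 gave 3752 to 4284 in vector and 1 to 12 in p53i, and p53i against vector 488 to 638. The interactions gave 10 to 62 (flagellin by Nutlin-3), 46 to 80 (flagellin by line), 2 to 4 (all 3 factors) and 1699 to 2125 (Nutlin-3 by line). The repeat arrays gave 0 in every case, flagellin with SB203580 0 to 47, and the SB203580 comparisons and their interaction 0 in every case. For 222 calls, each of a gene in a comparison, 1354 of 1555 such values kept the call and 201 lost it.

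Signals without a stated background limit all of this, because settings that treat dim signals differently all start from the same MAS5 values and cannot show which dim signals were real.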

Other observations

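No test in this part was chosen after its result was seen.

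Estrogen response genes, a class MCF-7 depends on, were mixed after Nutlin-3 in vector (4 up and 6 down of 24, also over the list alone; adjusted p = 0.66), and CCND1, cyclin D1, rose 3.2-fold. Flagellin raised 3 and lowered 0 with vector DMSO (adjusted p = 0.294) and raised 3 and lowered 5 with vector Nutlin-3 (adjusted p = 0.685, median -0.144, mean 0.01). Cholesterol synthesis genes were mixed after Nutlin-3 in vector (3 up and 6 down of 16, 3 and 7 over the list alone; adjusted p = 0.165), with EBP down 2.43-fold and SC5D up 1.74-fold, a rise that was gone with the mean of its probe sets (-0.027, adjusted p = 0.957). The flagellin comparisons in p53i called this list higher with DMSO (2 and 0 of 16, 4 and 0 over the list alone; adjusted p = 0.0415, adjusted p = 0.549 with an estimated correlation) and with Nutlin-3 (2 and 0, 4 and 0 over the list alone; adjusted p = 0.021, adjusted p = 0.509 with an estimated correlation). Stress response genes split after Nutlin-3 in vector (5 up and 4 down of 18, also over the list alone; adjusted p = 0.937), with a median of 0.008, a mean of -0.042 and a positive test. SESN2 rose 3.97-fold and DDIT4, an inhibitor of mTORC1, rose 3.66-fold. That list was called higher with flagellin in p53i DMSO (4 and 0 of 18; adjusted p = 0.00535, adjusted p = 0.267 with an estimated correlation) and p53i Nutlin-3 (5 and 1, 7 and 1 over the list alone; adjusted p = 0.00171, adjusted p = 0.2 with an estimated correlation).

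p38 MAPK pathway components were called in no comparison. After Nutlin-3 in vector 4 rose and 2 fell of 14 (adjusted p = 0.296), and with flagellin 0 rose and 1 fell in vector DMSO (0 and 2 over the list alone; adjusted p = 0.526) and 1 rose and 1 fell in vector Nutlin-3 (adjusted p = 0.821). Interferon-stimulated genes after Nutlin-3 in vector were 1 up and 6 down of 29, also over the list alone (adjusted p = 0.321). Their median (0.072) was positive and their mean (-0.087) and test were negative, with HERC5 2.2-fold lower. Among markers, basal or mesenchymal epithelial genes rose with Nutlin-3 in vector (5 and 0 of 5; adjusted p = 0.0062, adjusted p = 0.453 with an estimated correlation) and in Nutlin-3 by line (3 and 0; adjusted p = 0.0062, adjusted p = 0.453 with an estimated correlation). After Nutlin-3 in vector leukocyte markers (1 up of 7; adjusted p = 0.465), fibroblast markers (2 up and 1 down of 7; adjusted p = 0.9) and luminal epithelial markers (5 up of 10; adjusted p = 0.42) were not called, and none of these was called elsewhere.

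Wherever the median, the mean and the test of a list differed in sign the list was not called. Besides those named here and in the report, this was so for estrogen response genes with flagellin in p53i DMSO (median -0.105, mean 0.169) and p53i Nutlin-3 (median -0.121, mean 0.133). It was also so for apoptosis regulators in p53i against vector (median 0.024, mean 0.028, negative test) and immediate early genes in flagellin by Nutlin-3 (median -0.009, mean -0.066, positive test).

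Single pairs of arrays differed in their mean NF-kB response. The log2 differences were 2.77, 2.593 and 3.108 for pairs 1, 2 and 3 of vector Nutlin-3, 1.663 and 2.214 for pairs 2 and 3 of vector DMSO, 2.916, 3.222 and 4.424 for the repeat pairs, and 2.596, 3.138 and -2.686 with SB203580.

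CDKN1A on the first arrays of vector Nutlin-3 was 21146, 22116 and 14846, and on those of p53i Nutlin-3 1639, 992 and 634. TLR5 had low signals throughout, with 57.9 ± 27.63 in vector DMSO and 124.3 ± 21.07 in vector Nutlin-3.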
